A study of Mus musculus with 18 samples.

How the data were processed

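RNA from 18 mouse libraries was measured by bulk sequencing of Smart-seq2 cDNA, per the labels' protocols. The labels place the libraries in 6 groups of 3: hepatic stellate cells (HSC) directly after isolation, HSC after 7 days on plastic, HSC after 7 days alone in Matrigel, HSC after 7 days in Matrigel with intrahepatic cholangiocyte organoids (ICO), ICO after 7 days alone in Matrigel, and ICO from the co-culture. The organoids carried a dTomato tag and the Matrigel cultures were sorted before RNA isolation, per the series design text. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

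The authors deposited estimated counts per gene and library, which need not be whole numbers. The submitters' processing notes name kallisto 0.46.1, DESeq2 1.36.0 and the mouse build GRCm39, without saying what each was used for. The annotation release, any filters and the way transcripts were summed to genes are not given in the sources used here. Gene symbols and Ensembl identifiers were taken from the deposited table, which holds 35667 genes. No coordinates are printed because the annotation at hand is of another build. Where a symbol occurred more than once, the row with the higher total kept it. Reads of near-identical genes, such as the major urinary protein (Mup) family and the small proline-rich (Sprr) family, may have been divided among members, so values of single members are uncertain.

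The deposited estimated counts were rounded to whole numbers. Each comparison was tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood test, TMM scaling, default low-count filter), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons among HSC groups used 1 fit of all HSC libraries. The ICO comparison used the 6 ICO libraries, and the comparisons across cell types used the 12 Matrigel libraries. Levels are CPM (counts scaled to library size), computed from the deposited counts with TMM factors over all 18 libraries, as mean ± SD over 3 libraries. Fold changes are fitted log2 values ± standard error (SE). The SE was taken as the absolute fitted change divided by the square root of the F value of the test. It is thus no estimate of error apart from the test, and it equals 0 where the fitted change is 0. Where all libraries of a group held 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Floors cover counting error only, since reads were not counted by molecular identifier.

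A total of 27 gene lists with 618 genes were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 27 lists of a comparison. Counts of list members are over all genes tested, with the count adjusted over the list alone beside them where it differs. For each of the 5 comparisons within a cell type the rule took the 6 genes with the largest fitted increase and the 6 with the largest decrease among genes past the threshold that had a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, leaving out clone names, pseudogenes and antigen receptor segments. The rule added from each list chosen for the cell type up to 2 called members per direction, at most 3 in all, and marker genes whatever their result. Some genes the rule names are not reported here.

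The test was checked on simulated counts with 200 changed genes. All groups otherwise had the same means, whereas 16.6% to 58% of genes were called in the real comparisons. The simulated recoveries hold for that setting and need not be the sensitivity reached in the real data. For HSC in co-culture against mono-culture, with 16287 genes tested, the test recovered 7.46% of 1.5-fold, 40.3% of 2-fold and 81.8% of 4-fold changes. For ICO in co-culture against mono-culture, with 13435 genes tested, it recovered 41.8%, 77.6% and 95.2%. Recovery was 5.97%, 35.8% and 78.8% for plastic against day 0 (16317 genes), 5.97%, 41.8% and 74.2% for Matrigel against day 0 (16330 genes), 4.48%, 44.8% and 77.3% for Matrigel against plastic (16323 genes) and 4.48%, 31.3% and 72.7% for HSC against ICO (15660 genes). For the difference of co-culture effects (15632 genes) it was 0%, 5.97% and 63.6%. False calls made up 6.49% of calls for HSC against ICO and 0% to 4.79% in the other comparisons. An organoid share was estimated for each library as the median, over 13 genes of the cholangiocyte list, of its level divided by the mean organoid level of the same culture. Those 13 genes had at least 100 CPM in both organoid groups and under 5 CPM in every day 0 and plastic library. This estimate was devised after the data were examined.

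Alternatives were RLE scaling, no low-count filter, a filter of at least 10 CPM in 3 libraries, DESeq2 1.42.0, other sets of fitted libraries, the replicate number as a block, and leaving out each library. Subtraction of the organoid share from the counts, the share as a covariate, and a replicate block for the co-culture libraries alone were added after the data were examined. No library was left out of the main comparisons. No replicate pair agreed within sampling noise: chi-square per degree of freedom over genes with at least 20 counts was between 5.9 and 72.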

Results

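Gene expression was measured in 18 bulk RNA libraries from mouse liver cells. HSC are the retinoid-storing pericytes of the liver, and ICO are organoids grown from bile duct epithelium. The 6 groups held 3 libraries each: HSC at day 0, HSC at day 7 on plastic, HSC at day 7 in Matrigel alone, HSC at day 7 in Matrigel with ICO, and ICO at day 7 in Matrigel alone or with HSC. Total counts ranged from 6907479 in co-cultured HSC replicate 1 to 22158674 in plastic HSC replicate 2. Between 19114 and 22550 genes had at least 1 count per library.

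**Figure D1:**
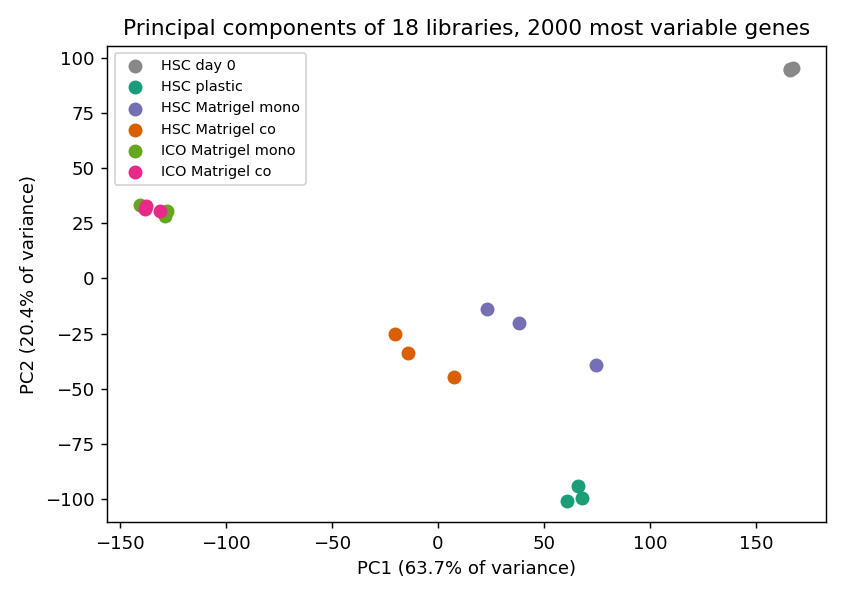
Each point is 1 library on principal components 1 and 2 of log2 CPM over the 2000 most variable genes, with the share of variance on each axis, coloured by group. The first component held 63.7% of the variance and ran from day 0 HSC to ICO, and the second held 20.4%, with plastic HSC at the lower end.

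HSC and ICO alone in Matrigel were first compared to establish which transcripts separate the cell types. Of 16233 genes tested, 5018 were higher in HSC and 4194 in ICO. Dcn (ENSMUSG00000019929), a matrix proteoglycan of mesenchymal cells, had 21190 ± 6340 CPM in HSC and 21.3 ± 18.7 CPM in ICO. Pdgfrb, a receptor of pericytes, was higher in HSC by 7.89 ± 0.73 (log2, adjusted p = 1.95e-05), and Col1a1 by 6.42 ± 0.46 (adjusted p = 8.57e-07). Of the epithelial genes, Epcam had 187 ± 170 CPM in HSC and 1088 ± 52.3 CPM in ICO, Cdh1 108 ± 90.1 and 673 ± 16.8 CPM, and Krt19 209 ± 220 and 1425 ± 97.6 CPM. Their adjusted p-values were 0.0114, 0.00558 and 0.0309. The Krt19 call was lost without HSC replicate 2 (adjusted p = 0.0942) and without ICO replicate 1, 2 or 3 (0.0613, 0.0602 and 0.0536), and without the filter (0.0596); over all alternatives it lay between 0.00368 and 0.0942.

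Cholangiocyte transcripts in the HSC libraries differed between culture conditions. The organoid share was 34.3%, 12.7% and 4.05% in replicates 1, 2 and 3 of HSC alone in Matrigel, and 28%, 14.5% and 41.9% in co-cultured HSC. It was at most 0.27% in the day 0 and plastic libraries. The labels place the HSC cultured alone apart from organoids, and whether organoid cells were mixed into these libraries or a library was mislabelled is not known, so values of HSC alone in Matrigel are those of the libraries so labelled. Macrophage transcripts summed to between 2656 and 3665 CPM in HSC alone in Matrigel, to between 149 and 230.2 CPM in co-cultured HSC, to between 125 and 564 CPM on plastic and to between 1014 and 1078 CPM at day 0. Transcripts of the hepatocyte list without Trf summed to between 32670 and 34030 CPM at day 0 and to at most 579 CPM in any later HSC library.

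**Figure D2:**
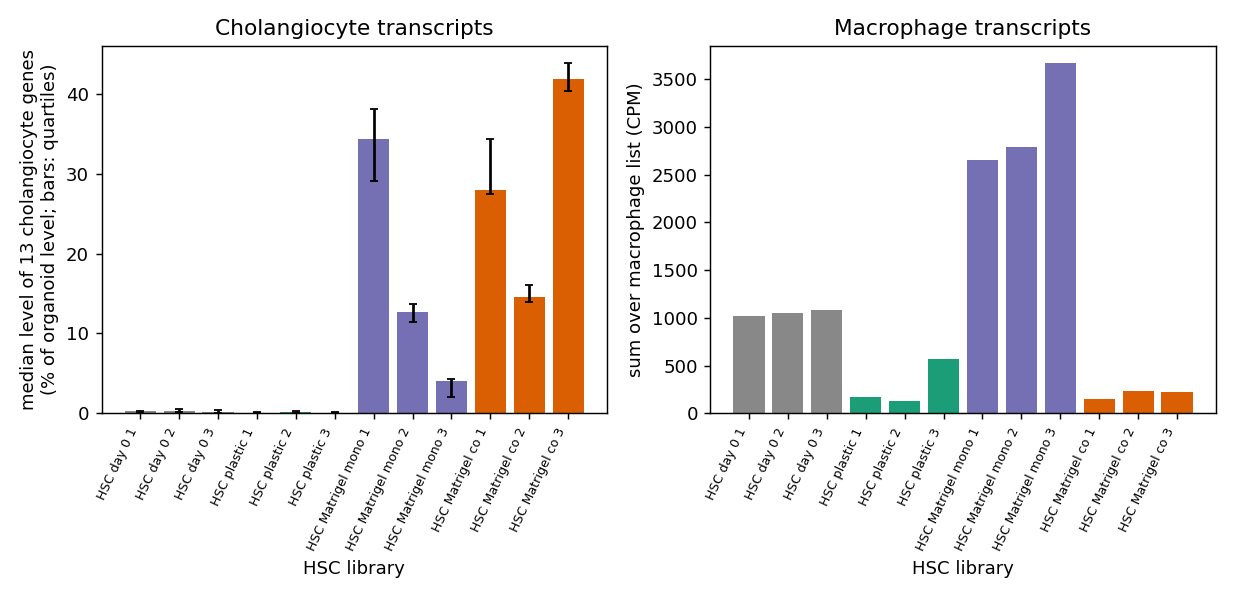
Bars give, for each of the 12 HSC libraries, the median level of 13 cholangiocyte genes as a percentage of the organoid level (left, with quartiles over genes) and the summed CPM of the macrophage list (right). The 6 Matrigel libraries lie between 4.05% and 41.9% on the left, and the 3 libraries of HSC alone in Matrigel reach at least 2656 CPM on the right.

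Culture on plastic was compared with freshly isolated cells. Of 17020 genes, 4678 were higher and 5192 lower after 7 days. Acta2 (ENSMUSG00000035783), the smooth muscle actin of activated HSC, had 4420 ± 752 CPM on plastic and 6.13 ± 2.23 CPM at day 0 (log2 fold change 9.56 ± 1.56, adjusted p = 0.000505). Timp1, an inhibitor of matrix proteases, increased by 7.05 ± 0.52 and Col1a1 by 2.58 ± 0.22 on the log2 scale (adjusted p = 7.12e-07 and 4.13e-07). Reln, a glycoprotein of quiescent HSC, fell by 4.55 and Lrat, the enzyme that esterifies retinol, fell by 3.06 (adjusted p = 4.37e-08 and 3.57e-05).

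Of 24 stellate quiescence genes, 20 were lower and 1 higher on plastic (20 and 2 adjusted over the list alone). Ecm1 fell by 4.94 and Pth1r by 6.73 on the log2 scale, while Nes was higher by 0.69 ± 0.26 (adjusted p = 0.0366). The Nes call was lost without day 0 replicate 1, 2 or 3 (adjusted p = 0.0868, 0.1 and 0.0819) or plastic replicate 2 or 3 (0.105 and 0.058), and without the filter (0.0565). All but 1 of 20 contractile and cytoskeletal genes were higher, 19 also adjusted over the list alone, among them Tpm1 (4.57 ± 0.24) and Pdlim7 (2.76 ± 0.16). Of 34 cell cycle genes 33 were higher, with Mki67 at 17 ± 4.28 against 1.8 ± 0.28 CPM, Birc5 at 41.9 ± 2.24 against 1.67 ± 0.43 CPM and Tk1 at 52.5 ± 4.18 against 5.3 ± 0.24 CPM. The camera adjusted p-values of the quiescence, contractile and cell cycle lists were 5.41e-09, 1.75e-09 and 8.3e-15, and each call was lost with an estimated correlation (adjusted p = 0.147, 0.147 and 0.251).

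Matrix genes moved both ways on plastic: 12 of 30 fibrillar matrix genes were higher and 13 lower (13 and 13 adjusted over the list alone), with Thbs1 higher by 5.48 ± 0.25, Col5a2 higher by 3.96 ± 0.21 and Thbs2 lower, a change of -2.57 ± 0.19. Of 19 basement membrane genes 5 were higher and 8 lower (6 and 8 over the list alone), including Col4a2 (1.74 ± 0.16), Lama1 (-4 ± 0.24) and Lamb2 (-1.37 ± 0.13). Of 24 matrix proteases and inhibitors 9 were higher and 9 lower, with Mmp3 at 7.01 ± 0.48, Plau at 3.4 ± 0.26 and Adamts1 at -1.29 ± 0.18. None of these 3 lists passed camera (adjusted p = 0.188, 0.801 and 0.171), but with only the 6 libraries compared the fibrillar matrix and protease lists did (0.00922 and 0.0126). Among 23 YAP/TAZ targets, 14 were higher, including F3 (7.48 ± 0.59) and Axl (2.63 ± 0.21), and 7 lower, including Igfbp3 (-4.61 ± 0.22), with an adjusted p of 0.166 (0.0257 without the filter and 0.00922 with only the 6 libraries). In the growth factor and cytokine lists, genes that were higher included Bdnf (7.71 ± 0.38), Ereg (5.45 ± 0.37), Lif (7.32 ± 0.56) and Csf1 (3.02 ± 0.21), while Bmp4 (-2.41 ± 0.21) and Nfkbia (-2.1 ± 0.18), an intracellular inhibitor of NF-kB, were lower. Those 2 lists had 7 higher and 16 lower of 39, and 6 higher and 14 lower of 29 (7 and 14 adjusted over the list alone), both with an adjusted p of 0.623.

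The largest decreases on plastic were in genes of hepatocyte secretion and metabolism, Mup1, Cps1, Mup10, F2, Mug1 and Slc27a2, all at 0 counts on plastic. Relative to the floor, Mup1 was at least 34800-fold and Slc27a2 at least 6800-fold lower. The hepatocyte list without Trf summed to between 32670 and 34030 CPM at day 0. Such decreases are those of whole libraries and are not shown to be changes within HSC. All 32 hepatocyte genes were lower (adjusted p = 7.16e-47, and 0.000149 with an estimated correlation), as were all 18 endothelial genes (6.25e-15, and 0.000788), 5 of 6 lymphocyte genes (0.0112, and 0.147) and 12 of 18 macrophage genes (0.00139, and 0.429). Of 13 mitochondrially encoded genes 12 were lower (0.00605, and 0.509), and together they took 1.81% to 2.5% of the counts on plastic and 3.91% to 4.8% at day 0. The largest increases, from 0 counts at day 0, were Mmp10 at 410 ± 73.5 CPM (at least 5740-fold), Sprr1a at 326 ± 66.6 CPM (at least 4570-fold), Hs6st2 (at least 1120-fold), Serpinb2 (at least 551-fold), Tnfsf18 (at least 481-fold) and Sprr2h (at least 344-fold).

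HSC alone in Matrigel were then compared with day 0. Of 17020 genes, 3279 were higher and 3667 lower. Reln had 2064 ± 520 CPM in Matrigel and 2564 ± 187 CPM at day 0 (log2 fold change -0.30 ± 0.26, adjusted p = 0.367), and Col1a1 120.2 ± 25.9 and 160.0 ± 6.57 CPM (adjusted p = 0.135). Lrat fell by 2.1 on the log2 scale (adjusted p = 0.000997) and Timp1 was higher by 2.19 ± 0.44 (adjusted p = 0.00253). Acta2 had 24.2 ± 38.3 CPM in Matrigel and 6.13 ± 2.23 CPM at day 0 (adjusted p = 0.215), and without Matrigel replicate 1 its log2 fold change was -1.47 (adjusted p = 0.0875).

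Of the quiescence list, 15 genes were lower and 2 higher in Matrigel than at day 0 (15 and 4 over the list alone), with Pth1r at -3.51 ± 0.24, Nes at -2.69 ± 0.28 and Hand2 at 1.06 ± 0.23. Nes moved against most of this list on plastic and in co-culture, so its decrease here is not read as a loss of quiescence. The adjusted p of the list was 0.0181, and 0.562 with an estimated correlation. That call was lost without Matrigel replicate 1 (0.0632), with the stricter filter (0.0951) and after subtraction of the organoid share (0.0683). Contractile genes included 3 higher and 8 lower, among them Csrp1 (0.70 ± 0.12), Vcl (-1.56 ± 0.11) and Flna (-1.3 ± 0.14). Of the fibrillar matrix list 6 were higher and 14 lower (7 and 14 adjusted over the list alone), including Plod2 (1.1 ± 0.15), Postn (-3.25 ± 0.21) and Serpinh1 (-1.76 ± 0.2). Of the basement membrane list 4 were higher and 9 lower (5 and 9 over the list alone), including Lama1 (-2.39 ± 0.22) and Nid1 (-1.4 ± 0.16). Protease genes Plau (3.18 ± 0.26), Mmp14 (0.99 ± 0.15) and Adamts1 (-2.01 ± 0.18) changed, in a list with 9 higher and 5 lower (10 and 5 over the list alone). YAP/TAZ targets had 4 higher and 12 lower, with Ankrd1 at 8.31 ± 1.07, Gadd45b at -2.58 ± 0.2 and Lats2 at -1.26 ± 0.13. The adjusted p-values of these 5 lists were 0.113, 0.181, 0.181, 0.258 and 0.114. Without the filter all but the protease list were called, with adjusted p of 0.00355, 0.0101, 0.012 and 0.00565. Without Matrigel replicate 1 the contractile and YAP/TAZ lists were (2e-05 and 0.0208), and after subtraction of the organoid share the basement membrane and YAP/TAZ lists were (0.0192 and 0.0143). With the share as a covariate the contractile and YAP/TAZ lists were (0.00474 and 0.000753).

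Cell cycle genes were higher in Matrigel than at day 0, 29 of 34 (adjusted p = 1.48e-13, and 0.47 with an estimated correlation), with Mki67 at 3.2 ± 0.32 and Birc5 at 3.61 ± 0.32. Genes of the cytokine and growth factor lists included Lif (4.87 ± 0.58) and Btc (2.42 ± 0.36) among those higher, and Cxcl10 (-5.86 ± 0.47), the adhesion receptor gene Icam1 (-1.92 ± 0.19) and Bmp4 (-2.65 ± 0.21) among those lower. These lists had 13 higher and 11 lower of 29 (14 and 12 adjusted over the list alone) and 13 higher and 11 lower of 39 (13 and 12), with adjusted p of 0.859 and 0.833. Among the largest increases were the epithelial or mucosal genes Mmp7, Gabrp, Ccl20, Sprr1a and Sprr2a3, and 25 of 28 cholangiocyte genes were higher (adjusted p = 3.29e-07, and 0.506 with an estimated correlation), in libraries whose organoid share was 34.3%, 12.7% and 4.05%. In those libraries Mmp7 had 425 CPM, 17.8 CPM and 45.4 CPM, against 57.3 to 129 CPM in ICO alone. After subtraction of that share, chosen after seeing the data, Ankrd1 (log2 fold change 4.6 ± 1.99, against 8.31 ± 1.07 before; adjusted p = 0.106), Btc (0.78 ± 0.8, against 2.42 ± 0.36; 0.481) and Sprr1a (1) were no longer called. Gabrp had 72.1 ± 79.6 CPM in Matrigel, and its call was lost when only the 6 libraries compared were fitted (0.111). The Sprr2a3 call was lost without Matrigel replicate 1 (0.0568) and with the share as a covariate (0.0906), as was that of Sprr1a with the covariate (0.0778). Both had 0 counts at day 0, and their fitted changes, which depend on the prior count, stayed large: 11.03 ± 3.53 and 9.91 ± 3.6 for Sprr2a3, against 11.63 ± 3.03, and 10.32 ± 3.54 for Sprr1a, against 12.01 ± 2.95. Sprr1a also reached 326 CPM on plastic, where the organoid share was at most 0.15%. The largest decreases were Mup22, Mup2, Mup9, Mup1, Mup3 and Apoa5, with Apoa5 at least 9330-fold lower. As on plastic, these decreases are not shown to be changes within HSC. Of the markers of other cell types, all 18 endothelial genes (adjusted p = 2.25e-30, and 0.000271 with an estimated correlation), 31 of 32 hepatocyte genes (4.7e-65, and 0.00237) and 5 of 6 lymphocyte genes were lower than at day 0. The lymphocyte list, with 1 higher and 5 lower over the list alone, had an adjusted p of 0.0136, 0.176 with an estimated correlation and 0.383 with the share as a covariate.

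Matrigel and plastic were compared at day 7. Of 17020 genes, 5081 were higher in Matrigel and 4283 lower. Acta2 fell by 7.59 on the log2 scale (adjusted p = 0.0016), Timp1 by 4.86 (adjusted p = 9.05e-06) and Col1a1 by 2.99 (adjusted p = 3.67e-07), while Reln was higher by 4.25 ± 0.29 (adjusted p = 2.33e-07). Lrat was higher by 0.96 ± 0.37 (adjusted p = 0.0438). That call was lost without plastic replicate 2 or 3 (adjusted p = 0.14 and 0.135), without Matrigel replicate 2 or 3 (0.105 and 0.15), without the filter (0.119), with all 18 libraries (0.084) and with only the 6 libraries compared (0.0809). Mki67 had 16.6 ± 7.16 CPM in Matrigel and 17 ± 4.28 CPM on plastic (adjusted p = 0.787).

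All 20 contractile and cytoskeletal genes were lower in Matrigel, including Tpm1 (-4 ± 0.23), Vcl (-1.96 ± 0.11), Tagln (-7.4 ± 0.98) and Cnn1 (-7.24 ± 0.89). Of 24 quiescence genes 20 were higher and 2 lower (21 and 3 adjusted over the list alone), with Ngfr at 6.05 ± 0.36 and Nes at -3.38 ± 0.29. YAP/TAZ targets had 15 lower and 3 higher of 23, with Axl (-4.49 ± 0.23), Ccn1 (-3.37 ± 0.24) and Igfbp3 (3.69 ± 0.21). The fibrillar matrix list had 17 lower and 11 higher, with Col5a2 (-4.49 ± 0.22), Thbs1 (-4 ± 0.23) and Col6a2 (3.02 ± 0.18). The cell cycle list had 16 lower and 0 higher of 34, with Rrm2 at -2.73 ± 0.33 and Ccne1 at -2.68 ± 0.35. Camera adjusted p-values were 4.39e-21, 1.08e-08, 0.000248, 0.000619 and 0.00203, and with an estimated correlation 0.0607, 0.29, 0.215, 0.469 and 0.678. After subtraction of the organoid share the fibrillar matrix list was not called (0.0764). Basement membrane genes had 9 higher and 6 lower (9 and 8 over the list alone), including Lamb2 (1.17 ± 0.13), Col4a1 (-2.83 ± 0.2) and Col4a2 (-2.4 ± 0.17), and proteases 6 higher and 8 lower, including Mmp2 (2.08 ± 0.25), Mmp3 (-5.13 ± 0.43) and Mmp13 (-6.36 ± 0.5). Both had an adjusted p of 0.442. All 13 mitochondrially encoded genes were higher in Matrigel (adjusted p = 1.13e-05, and 0.42 with an estimated correlation), where they took 5.07% to 8.6% of the counts against 1.81% to 2.5% on plastic.

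Genes of secreted or membrane-bound factors that were lower in Matrigel than on plastic included Bdnf (-6.18 ± 0.35), Ereg (-5.66 ± 0.38), Il6 (-5.35 ± 0.53), Csf1 (-2.21 ± 0.21), Tnfsf18 (-7.35 ± 0.87) and the protease gene Mmp10 (-7.32 ± 1.23), while Gas6 (4.66 ± 0.41) and Cxcl16 (1.7 ± 0.21) were higher. Without Matrigel replicate 1 the log2 fold changes of Mmp10 and Tnfsf18 were -12.07 and -12.09. The cytokine and growth factor lists had 17 higher and 7 lower of 29 (18 and 7 adjusted over the list alone) and 15 higher and 7 lower of 39, with adjusted p of 0.428 and 0.604. Fez1 had 13.6 ± 1.35 CPM on plastic and 3 counts in all in Matrigel. The largest increases were the epithelial genes Tmprss4, Mab21l4, Epn3, Eps8l3, Tmprss2 and Cdh1, and all but 1 of 28 cholangiocyte genes and 14 of 18 macrophage genes were higher (adjusted p = 2.7e-08 and 0.00024, and 0.421 and 0.42 with an estimated correlation), in the libraries with the organoid shares given above and macrophage sums of at least 2656 CPM. Hepatocyte genes had 16 higher and 0 lower of 32 (camera adjusted p = 0.00323, and 0.42 with an estimated correlation). Endothelial genes had 3 higher and 11 lower of 18 (0.0106, and 0.29). After subtraction of the organoid share the Cxcl16 log2 fold change was 1.47 ± 0.8, against 1.7 ± 0.21 before, and Cxcl16 was no longer called (adjusted p = 0.157). Cdh1, whose own level entered the share, was also no longer called (4.36 ± 1.75, against 9.73 ± 1.06 before; 0.0593). Tmprss2 and Eps8l3, with 1 and 0 counts on plastic, had fitted changes of -1.66 ± 4.63 (against 10.1 ± 1.67; 0.793) and 7.74 ± 2.85 (against 10.23 ± 2.23; 0.0583), values that depend on the prior count, and were not called either. With only the 6 libraries compared the Tmprss4 call was lost (0.0594).

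Co-culture with organoids was compared with culture alone in Matrigel to see how HSC differed when organoids shared the gel. Of 17020 genes, 2949 were higher in co-cultured HSC and 2341 lower. Col1a1 (ENSMUSG00000001506), the main chain of fibrillar collagen, had 3165 ± 1010 CPM in co-culture and 120.2 ± 25.9 CPM alone (log2 fold change 4.76 ± 0.24, adjusted p = 3.56e-08). Timp1 was higher by 5.07 ± 0.46 (adjusted p = 1.55e-05) and Acta2 by 4.78 ± 1.26 (adjusted p = 0.0175), from 24.2 ± 38.3 to 633 ± 143 CPM. Reln (ENSMUSG00000042453) fell from 2064 ± 520 to 130 ± 6.61 CPM (adjusted p = 5.92e-07). Lrat had 688 ± 286 CPM in co-culture and 518 ± 129 CPM alone (adjusted p = 0.381). With only the 6 libraries compared in the fit, 1605 genes were higher and the Acta2 call was lost (adjusted p = 0.103), while without mono-culture replicate 1 the Acta2 log2 fold change was 8.22 (adjusted p = 2.14e-05); its adjusted p lay between those values under every other alternative.

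**Figure D3:**
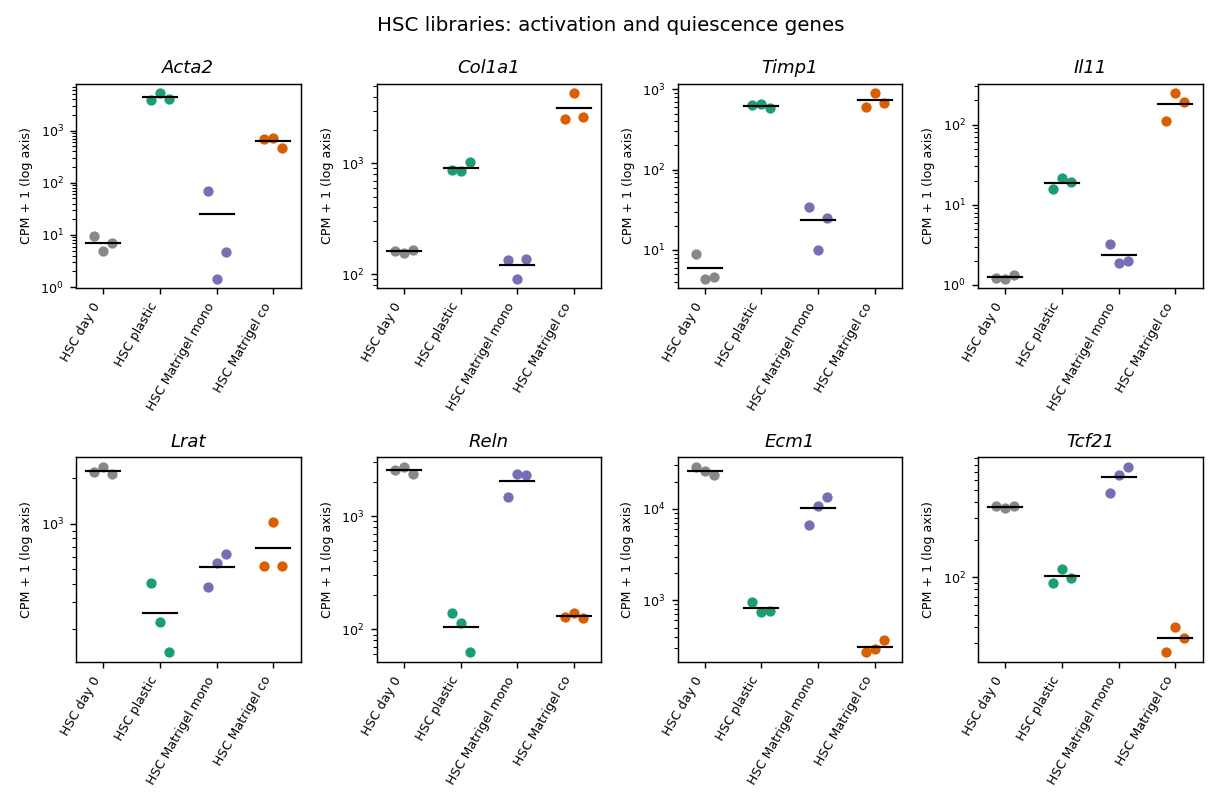
CPM + 1 on a log axis for 8 genes in the 12 HSC libraries; points are libraries, black lines are means of 3, and no error bars are drawn. Co-cultured HSC lie above HSC alone in Matrigel for Acta2, Col1a1, Timp1 and Il11, and below them for Reln, Ecm1 and Tcf21.

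Of 30 fibrillar matrix genes 19 were higher and 6 lower in co-cultured HSC (20 and 7 adjusted over the list alone), with Col5a2 at 899 ± 263 against 83.5 ± 16.7 CPM and Col6a2 at 124 ± 21.1 against 345 ± 76.6 CPM. Of 20 contractile and cytoskeletal genes 18 were higher and 0 lower, among them Tagln2 (2.21 ± 0.24) and Tpm4 (1.93 ± 0.19). The quiescence list had 18 lower and 1 higher of 24: the transcription factor Tcf21 had 31.5 ± 7.44 against 634 ± 151 CPM, Ecm1 307.6 ± 49.3 against 10320 ± 3470 CPM, and Nes, an intermediate filament gene, was higher by 3.16 ± 0.29. Camera adjusted p-values of these 3 lists were 3.7e-12, 9.09e-11 and 1.98e-18, and with an estimated correlation they were not called (adjusted p = 0.101, 0.0788 and 0.0788). The fry test, which asks whether a list's genes move one way on balance, gave 0.000103, 2.64e-05 and 5.39e-05. It does not compare a list with other genes, so it does not offset the lost camera calls. In this comparison fry also gave 9.31e-05 for the unfolded protein response and 0.00013 for the Wnt list. Lists not called by camera passed it too, such as contractile genes in Matrigel against day 0 (fry adjusted p = 0.00563). Basement membrane genes had 8 higher and 1 lower of 19 (adjusted p = 0.000392, and 0.043 with an estimated correlation), including Col4a1 (1.79 ± 0.19), Col4a2 (1.55 ± 0.16) and Lama2 (-2.12 ± 0.23).

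Proteases and inhibitors had 9 higher and 5 lower of 24 (9 and 6 adjusted over the list alone; adjusted p = 0.0199, 0.189 with an estimated correlation and 0.0715 with the stricter filter), with Mmp9 at 59.6 ± 21 against 0.33 ± 0.062 CPM and Plau at 11.9 ± 2.42 against 39.9 ± 11.4 CPM. YAP/TAZ targets had 10 higher and 2 lower of 23 (10 and 3 over the list alone; 0.0199, 0.224 with an estimated correlation, 0.0715 with the stricter filter and 0.0926 after subtraction of the organoid share), including Axl (2.43 ± 0.21), Ccn1 (1.93 ± 0.23) and Asap1 (-1.2 ± 0.12). Of 34 cell cycle genes 19 were higher and 0 lower (23 and 0 over the list alone, adjusted p = 3.05e-05, and 0.434 with an estimated correlation), including E2f1 (1.66 ± 0.28) and Ccne1 (1.72 ± 0.34). Mki67 had 29.1 ± 5.04 against 16.6 ± 7.16 CPM (adjusted p = 0.0305), a call lost without mono-culture replicate 2 or 3 (0.126 and 0.117), without co-culture replicate 1 or 2 (0.0928 and 0.0623), with only the 6 libraries compared (0.0866) and with the organoid share as a covariate (0.0527). Its log2 fold change lay between 0.67 and 0.86 in those fits (0.75 ± 0.27 with the covariate), against 0.86 in the main fit.

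Among secreted factors, Il11 had 182 ± 69.5 CPM in co-cultured HSC and 1.38 ± 0.78 CPM alone (log2 fold change 7.09 ± 0.38, adjusted p = 1.01e-07). Il6 (4.87 ± 0.52), Wnt2 (3.99 ± 0.39) and Fgf2 (2.75 ± 0.22) were higher, and Bmp5 (-2.43 ± 0.22) and Csf1 (-1.95 ± 0.21) lower. The growth factor list had 14 higher and 6 lower of 39 (15 and 6 adjusted over the list alone, adjusted p = 0.00809, and 0.0788 with an estimated correlation), and the cytokine list 6 higher and 11 lower of 29 (0.721). The largest increases were Cthrc1 at 221.5 ± 34.2 against 0.15 ± 0.21 CPM, Arg1 at 169 ± 90.1 against 0.28 ± 0.26 CPM, Defa29 at 16.6 ± 3.96 CPM against 0 counts (at least 265-fold), and Tnfsf8, Chl1 and Tmem59l at 898, 1039 and 813 counts in all against 1, 2 and 2 counts. The largest decreases were Itih4 (513 ± 276 to 2.54 ± 1.56 CPM), Mamdc2 (301 ± 71.8 to 1.43 ± 2 CPM), Cd36 (54.5 ± 25 to 0.35 ± 0.32 CPM), Egfem1 (74.5 ± 8.37 to 0.49 ± 0.48 CPM), Fam180a (62 ± 15.7 to 0.23 ± 0.36 CPM) and Akr1c14, at 13.8 ± 20.1 CPM alone and 1 count in co-culture. The Akr1c14 call was lost without co-culture replicate 2 or 3 (adjusted p = 0.0849 and 0.0625). In the same comparison 14 of 18 macrophage genes were lower (15 over the list alone, adjusted p = 4.85e-08, and 0.189 with an estimated correlation). The mesothelial and portal fibroblast list had 6 higher and 3 lower of 17 (camera adjusted p = 0.00338, and 0.0788 with an estimated correlation).

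Genes that changed on plastic were examined in co-culture, a comparison that shares no library with plastic against day 0. Of 2928 genes at least 2-fold higher on plastic, 1185 were higher and 76 lower in co-cultured HSC (camera p = 3.43e-17, estimated correlation p = 0.0145). Of 3795 genes at least 2-fold lower on plastic, 284 were higher and 1229 lower (camera p = 1.72e-13, estimated correlation p = 0.00133). The median log2 fold changes in co-culture were 0.55 and -0.51. Over all 17020 genes tested, 2949 were higher and 2341 lower in co-cultured HSC. Across those genes the log2 fold changes on plastic and in co-culture had a correlation of only 0.289. Macrophage genes were lower in both comparisons, 12 of 18 on plastic and 14 of 18 in co-culture (camera adjusted p = 0.00139 and 4.85e-08, and 0.429 and 0.189 with an estimated correlation), and all 32 hepatocyte and all 18 endothelial genes were lower on plastic.

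Organoids from co-culture were compared with organoids alone. Of 13726 genes, 1179 were higher in co-culture and 1093 lower. The counts were 763 and 664 without mono-culture replicate 1, and 785 and 721 without co-culture replicate 1. Mmp7 (ENSMUSG00000018623), the protease matrilysin, had 1450 ± 337 CPM in co-culture and 90.0 ± 36.3 CPM alone (log2 fold change 4 ± 0.39, adjusted p = 0.00246). Cell cycle genes were lower, 33 of 34 (adjusted p = 1.12e-53, and 0.0886 with an estimated correlation), with Rrm2 at 43.4 ± 3.08 against 109 ± 9.29 CPM, Top2a at 40.1 ± 7.48 against 92.4 ± 4.72 CPM and Mki67 at 9.69 ± 4.62 against 20.8 ± 2.98 CPM. Lgr5, a Wnt target and stem cell marker, was higher by 0.70 ± 0.1 (adjusted p = 0.000152). Krt19 (adjusted p = 0.19), Sox9 (0.656) and Alb (0.576, at 1.41 ± 1.29 and 2.09 ± 0.58 CPM) were not called. Epcam had 1350.0 ± 79.8 against 1088 ± 52.3 CPM (adjusted p = 0.0596), and was called without the filter (0.0232), with DESeq2 (0.00365) and without co-culture replicate 3 (0.0306), in a range from 0.00365 to 0.86 over all alternatives.

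**Figure D4:**
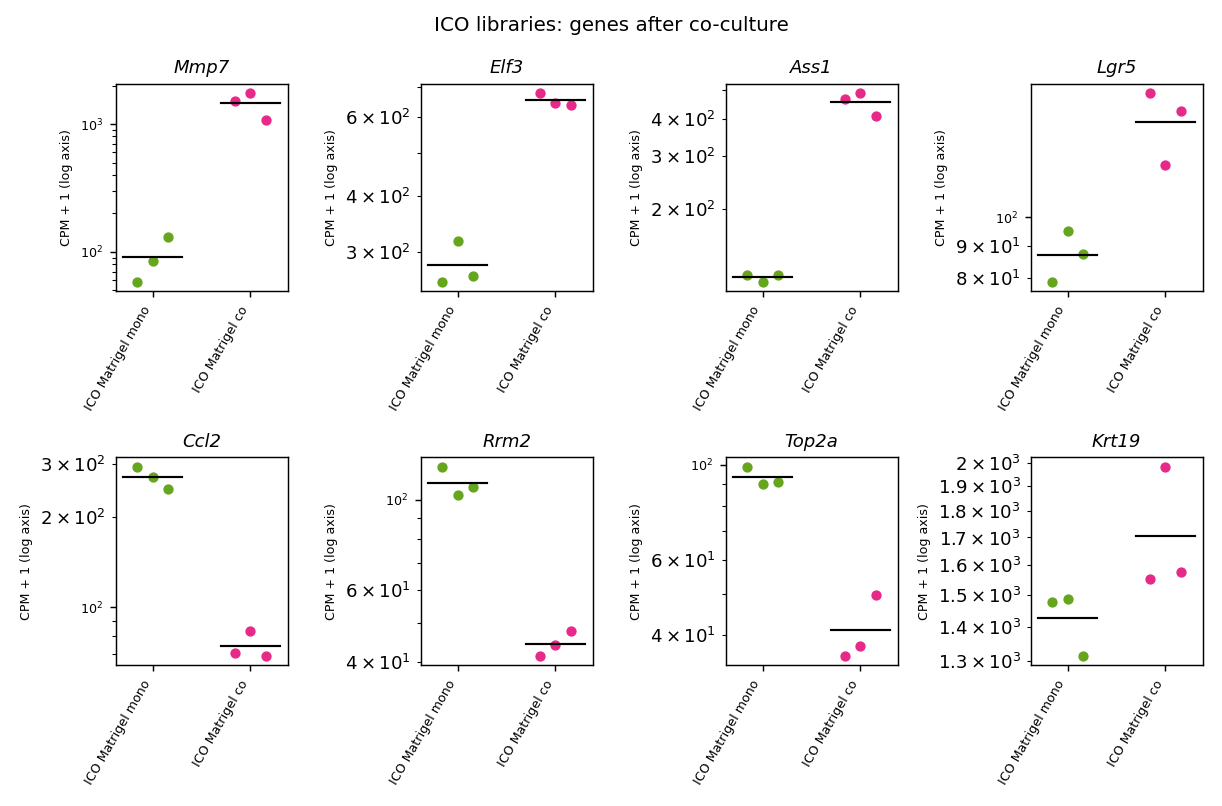
CPM + 1 on a log axis for 8 genes in the 6 ICO libraries; points are libraries, black lines are means of 3, and no error bars are drawn. Mmp7, Elf3, Ass1 and Lgr5 are higher in co-culture, Ccl2, Rrm2 and Top2a are lower, and Krt19 was not called.

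Cytokine and chemokine genes were lower in co-cultured organoids, 14 of 24 with 2 higher (17 and 3 adjusted over the list alone, adjusted p = 5.53e-16, and 0.0767 with an estimated correlation). Ccl2 had 73.3 ± 8.06 against 269.8 ± 23 CPM and Ccl20 18.8 ± 2.48 against 67.6 ± 3.84 CPM, while Lcn2 was higher by 0.72 ± 0.14. Of 28 cholangiocyte genes 7 were higher and 3 lower (10 and 3 over the list alone, adjusted p = 0.00598, and 0.171), with Elf3 (1.21 ± 0.1) and Krt8 (-0.47 ± 0.13). The Krt8 call was lost without mono-culture replicate 1 or 2 (adjusted p = 0.123 and 0.0931) or co-culture replicate 1 (0.105). Of 11 measured hepatocyte genes 4 were higher and 2 lower (6 and 2 adjusted over the list alone, 6.95e-05, and 0.208), including the urea cycle enzyme Ass1 (1.95 ± 0.097), the fibrinogen chain Fga (2.05 ± 0.24) and Hpx (-0.88 ± 0.19).

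Growth factors included 11 higher and 3 lower of 28 (12 and 3 adjusted over the list alone, adjusted p = 0.0196, and 0.183 with an estimated correlation), a list call lost without mono-culture replicate 2 or 3 (0.0502 and 0.101) or co-culture replicate 2 (0.0655), with Vegfa (1.14 ± 0.14), Pdgfc (1.15 ± 0.12) and Ereg (-1.23 ± 0.16). YAP/TAZ targets had 5 higher and 4 lower of 23 (6 and 5 over the list alone, 0.623), with Ccn2 (0.89 ± 0.12), Ankrd1 (-0.54 ± 0.093) and Axl (-2.03 ± 0.26). Basement membrane genes had 6 higher and 1 lower of 15 (7 and 1 over the list alone, 0.126, and 0.0336 without co-culture replicate 2), with Lama3 (0.79 ± 0.13), Lamb3 (0.46 ± 0.087) and Col18a1 (-0.48 ± 0.1). The Wnt list had 1 higher and 1 lower of 15 (0.944), the latter Ccnd1 (-0.51 ± 0.099). The Notch list had 1 lower of 12 (2 higher and 3 lower over the list alone, 0.976), Jag1 at -0.33 ± 0.1 (adjusted p = 0.0363), whose call was lost without mono-culture replicate 1, 2 or 3 (0.0554, 0.088 and 0.13) or co-culture replicate 1 or 2 (0.105 and 0.119). Other large increases were those of Lypd8l (3.05 ± 0.24) and Adm (2.59 ± 0.18). The largest decreases, besides that of Axl given above, were Olfm4 (-2.61 ± 0.3), Serpine2 (-2.53 ± 0.13), Inpp4b (-2.46 ± 0.35), Ppbp (-2.22 ± 0.25) and Aldh1a2 (-1.95 ± 0.19). Mesenchymal identity genes had 5 higher and 1 lower of 14 (5 and 2 over the list alone; adjusted p = 0.027, 0.57 with an estimated correlation and 0.634 without mono-culture replicate 3), with Col3a1 at 30.0 ± 16 against 0.19 ± 0.22 CPM, Col1a1 at 14.96 ± 6.96 against 1.48 ± 0.71 CPM and Cdh2 at 9.34 ± 1.51 against 25.2 ± 4.15 CPM. Co-cultured HSC had 10820 CPM of Col3a1. With all 18 libraries in 1 fit, 308 genes were higher and 238 lower in co-cultured organoids. That fit ended the calls of Aldh1a2, Ankrd1, Ccn2, Ccnd1, Col18a1, Elf3, Fga, Hpx, Jag1, Krt8, Lama3, Lamb3, Lcn2, Lgr5, Mki67, Olfm4, Pdgfc and Ppbp, with adjusted p from 0.0674 for Mki67 to 0.835 for Krt8, and of the cholangiocyte, hepatocyte and growth factor lists (0.808, 0.412 and 0.454).

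**Figure D5:**
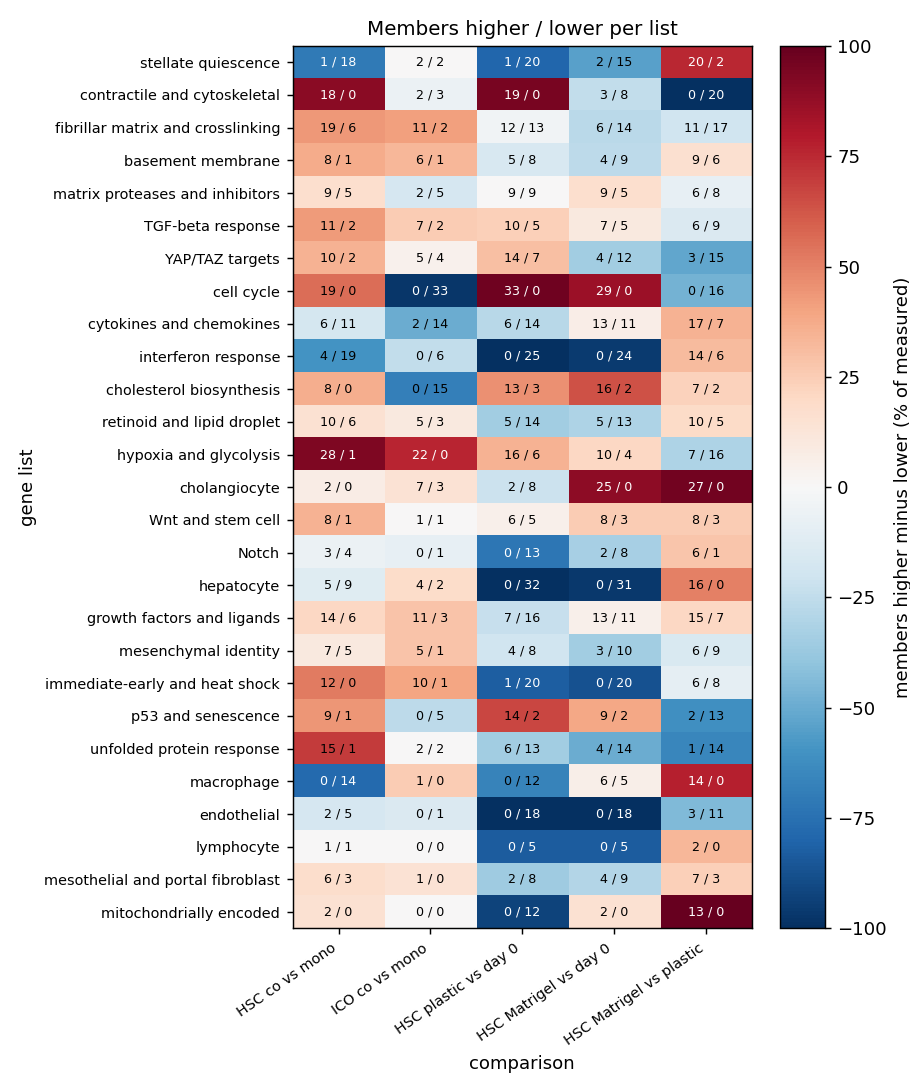
Rows are the 27 gene lists and columns the 5 comparisons; cells give the number of members called higher / lower, and colour the difference as a percentage of measured members. Cell cycle genes were higher in co-cultured HSC, 19 of 34 (23 adjusted over the list alone), and lower in co-cultured ICO, 33 of 34.

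The difference between the co-culture effects in HSC and ICO was tested in 1 fit of the 12 Matrigel libraries. Of 16233 genes, the effect was greater in HSC for 1474 and smaller for 1311. For Il11 the log2 fold change in HSC exceeded that in ICO by 8.27 ± 0.65 (adjusted p = 2.5e-05) and for Timp1 by 4.69 ± 0.5 (adjusted p = 2e-04). The cell cycle list differed, with 28 of 34 genes greater in HSC (34 adjusted over the list alone; adjusted p = 2.94e-20, and 0.24 with an estimated correlation). Without mono-cultured HSC replicate 1 the effect was greater in HSC for 2308 genes, and without mono-cultured ICO replicate 3 for 982.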

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

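All tests weighed for the 3 patterns in this part were chosen after the values they bear on had been seen in part; the counts over other groupings of the libraries were planned before.

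Co-culture effects that differed between HSC and ICO were found for 31 of 78 genes and for 17 of 27 lists. The 78 genes were those named for co-culture in HSC or in ICO, most of them chosen for a large or clear change in these same libraries. Such a choice favours a difference, so their share cannot be read against the 17.2% (2785 of 16233) called over all genes. The log2 fold change in HSC exceeded that in ICO by 9.1 for Aldh1a2, 8.27 for Il11, 7.86 for Cthrc1, 7.39 for Arg1, 7.04 for Serpine2, 5.04 for Ereg, 4.69 for Timp1, 4.37 for Axl, 3.47 for Nes, 3.26 for Ccne1, 2.64 for Rrm2, 2.18 for Top2a, 2.09 for Tagln2, 2.00 for Tpm4, 1.96 for Fgf2, 1.9 for Col4a1, 1.88 for Mki67, 1.65 for Ccn1, 1.45 for Col4a2, 1.39 for E2f1, 1.35 for Cdh2 and 0.78 for Jag1. It was below that in ICO for Ecm1 (difference -5.6), Adm (-3.31), Col3a1 (-3.12), Reln (-2.76), Ass1 (-1.61), Csf1 (-1.41) and Asap1 (-1.35). For Chl1 and Tmem59l, with 2 counts in a group, only the adjusted p is given (7.28e-05 and 0.018). Cthrc1, Col3a1 and Arg1 had 7, 8 and 14 counts in their lowest group, so the sizes of their differences are uncertain. HSC RNA carried through the sort, weighed below, may also have given the Col3a1 increase in co-cultured ICO. Its difference is thus not shown to be a greater effect within organoid cells.

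Lists whose co-culture effects differed by camera were cell cycle (adjusted p = 2.94e-20), hypoxia and glycolysis (4.74e-12), contractile and cytoskeletal (6.26e-08), cholesterol biosynthesis (0.000122), stellate quiescence and p53 and senescence (both 0.000288), macrophage (0.000424), Wnt and stem cell (0.00202), unfolded protein response (0.00328), basement membrane (0.00464), matrix proteases and inhibitors (0.0159), immediate-early and heat shock (0.0164), mesothelial and portal fibroblast (0.0211), fibrillar matrix (0.0292), YAP/TAZ targets and growth factors (both 0.0466) and TGF-beta response (0.0475). With an estimated correlation none was called, with adjusted p from 0.24 to 0.421. Leaving out 1 library also ended some calls: TGF-beta (HSC alone 2, co-cultured HSC 2 or 3, co-cultured ICO 1 or 3, 0.0527 to 0.114), YAP/TAZ (co-cultured HSC 1 or 3, co-cultured ICO 2, 0.0566 to 0.0846), growth factors (co-cultured HSC 1 or 3, ICO alone 1, co-cultured ICO 1, 2 or 3, 0.0507 to 0.114), fibrillar matrix (co-cultured HSC 2, co-cultured ICO 2, 0.0649 to 0.0809), mesothelial (HSC alone 2, ICO alone 3, 0.0509 and 0.0716) and immediate-early (co-cultured HSC 3, 0.0846). Labels of co-culture were exchanged within each cell type in 100 groupings, and 1 of 100, the real one, called as many as 2785 genes. The highest other count, 2692, came from the grouping that only exchanges the organoid labels, which keeps the HSC effect whole, and the next was 1763. Such exchanges ask whether co-culture had any effect, so they do not show whether the effects differ between HSC and ICO beyond chance.

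The first pattern was that of cholangiocyte transcripts in HSC from Matrigel: in the 3 co-culture libraries at least 97.6% of 42 organoid-only genes lay within 2-fold of 1 common ratio to the organoid level, which argues against HSC having switched on part of the cholangiocyte programme and is consistent with organoid cells or RNA carried through the sort. In HSC cultured alone, replicates 1 and 2 gave at least 95.2%, so organoid RNA may be present there too. Replicate 3, with a common ratio of 1.51%, gave 38.1%, and Sox9, Spint1 and Kcnn4 lay over 4 times above that ratio. One common ratio thus does not describe replicate 3. Its organoid share of 4.05%, which entered the subtraction and the covariate, is uncertain. Cholangiocytes already in the HSC preparation that grew in Matrigel could give the composition of replicates 1 and 2. The slope of replicate 1 on the organoid co-culture change was 0.27 ± 0.14, but the co-culture libraries themselves gave only 0.29 to 0.61, so the sources cannot be told apart. In replicate 1, Muc1 had 78.8 CPM, above every organoid library (means of 9.19 CPM in ICO alone and 8.68 CPM in ICO from co-culture), and Mmp7 had 425 CPM, above the 57.3 to 129 CPM of ICO alone and below the 1083 to 1746 CPM of ICO from co-culture; both genes were chosen after their values were seen, and their source stays open. Whether organoid cells were mixed into these libraries or a library was mislabelled is not told by the common ratio and stays open too, although macrophage transcripts, at 2656 to 3665 CPM in HSC alone and 149 to 230.2 CPM in co-cultured HSC, set the groups apart.

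Higher fibrillar matrix transcripts in co-cultured HSC were weighed next. The organoid share accounted for a median of 0.165% of the increase over the 19 genes called higher, at most 11% for Fn1, which argues against organoid RNA as the source. Fewer macrophages alone would raise every HSC transcript alike, whereas 6 genes of the same list were lower. Those 6 speak only against an equal rise of every transcript as the whole account. Whether the lower macrophage share added to the increase is not decided by them and stays open. A response of HSC to the organoids, and selection of a subset of HSC during culture or sorting, stay open and were not tested. The mesothelial and portal fibroblast list also had 6 genes higher and 3 lower of 17 in co-cultured HSC (camera adjusted p = 0.00338, and 0.0788 with an estimated correlation). What that means for the matrix genes was not tested.

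Mesenchymal transcripts in co-cultured ICO were weighed last. HSC-only genes had at least 200 CPM in co-cultured HSC and under 2 CPM in replicate 3 of ICO alone. Replicates 1 and 2, with macrophage sums of 59.3 and 43.9 CPM against 17.7 CPM in replicate 3, were not held to that limit. These genes are thus not shown to be absent from all organoids cultured alone. Of 43 such genes, 86% lay within 2-fold of 1 common ratio, 0.376% of the co-cultured HSC level. That argues against organoid cells having switched on single mesenchymal genes, and HSC cells or RNA carried through the sort could give it. The higher Col1a1 and Col3a1 of co-cultured organoids are among the transcripts such carry-over may bring.

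The 6 libraries of each comparison of 3 against 3 form 10 groupings, the real one included, too few for a share under 0.05. The real and highest other counts were 5290 and 0 for HSC in co-culture, 2272 and 0 for ICO in co-culture, 9870 and 0 for plastic, 6946 and 0 for Matrigel against day 0, 9364 and 0 for Matrigel against plastic, and 9212 and 0 for HSC against ICO. In each, 1 of the 10, the real grouping, reached its count.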

How the results depend on the processing

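Subtraction of the organoid share, the share as a covariate and a block for the co-culture libraries alone were chosen after the data were seen; the other alternatives were planned. RLE scaling, no filter, the stricter filter, DESeq2 and the replicate block kept every count of called genes within 1.5 times its main value. The labels share replicate numbers between groups, but same-numbered libraries did not deviate together (correlations from -0.25 to 0.059, and not every library correlated best with its own number), so the numbers are not taken to pair libraries. The titles of co-cultured HSC and ICO also share a letter, without saying that a pair came from 1 culture, and these pairs had correlations of 0.036, 0.03 and -0.0098. The main fit took all libraries as independent, and such low values between cell types do not exclude a shared culture for these pairs. With a replicate block for them alone, the co-culture effect was greater in HSC for 1280 genes and smaller for 1242, with 2401 of 2785 calls kept in the same direction, and the TGF-beta, YAP/TAZ and growth factor lists were not called (0.0654, 0.0604 and 0.0551). With the replicate block 2682 genes were higher and 2121 lower in co-cultured HSC, and 1053 higher and 997 lower in co-cultured ICO. The block ended the calls of Sprr2a3 in Matrigel against day 0 (adjusted p = 0.0507), of Lrat in Matrigel against plastic (0.0573), and of the protease and mesenchymal lists in co-cultured HSC (0.136 and 0.151). With only the 6 libraries compared, 1605 genes were higher in co-cultured HSC, and with all 18 libraries fitted 308 were higher and 238 lower in co-cultured ICO. That last fit estimates 1 spread for all groups, with a common dispersion of 0.0652 among the HSC libraries and 0.019 among the ICO libraries; the cause of the first was not tested. After subtraction of the organoid share 3242 genes were higher and 2612 lower in co-cultured HSC, and 4806 of the 5290 calls were kept in the same direction. In Matrigel against day 0, 2287 were higher and 3351 lower, with 19 calls opposite.

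Leaving out 1 library at a time, co-cultured HSC had 2038 to 3607 genes higher and 1748 to 2492 lower, and co-cultured ICO 763 to 1005 higher and 664 to 966 lower. The low ICO counts came without mono-culture replicate 1 (763 and 664) and without co-culture replicate 1 (785 and 721). Plastic against day 0 had 4082 to 4492 higher and 4632 to 4958 lower, Matrigel against day 0 2245 to 3015 and 3135 to 3558, Matrigel against plastic 4167 to 4851 and 3645 to 4378, and HSC against ICO 4292 to 4967 and 3427 to 4706. The difference of co-culture effects was called greater in HSC for 982 to 2308 genes and smaller for 916 to 1470. The cause was not tested. Median log2 fold changes in co-culture of genes higher and lower on plastic were 0.50 to 0.69 and -0.55 to -0.46.

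In co-cultured ICO the camera direction of the stellate quiescence and macrophage lists, not called before (adjusted p = 0.829 and 0.439, medians -0.091 and 0.33), turned from higher to lower and was called with all 18 libraries (0.00297 and 0.0106, medians -1.01 and -1.24) and without mono-culture replicate 3 (0.00561 and 0.0221, medians -1.01 and -2.77); without 1 library their medians ranged up to 0.041 and 0.28. In Matrigel against day 0 the direction reversed for Acta2 without Matrigel replicate 1 (-1.47, against up to 2.54 without others) and with the share as a covariate (-0.51), while the fitted change of Sprr1a was 0 after subtraction of the share, which leaves no direction. In Matrigel against plastic it reversed for Tmprss2 after subtraction (-1.66) and for Mki67 with the stricter filter (0.021) and without plastic replicate 2 (0.078) or Matrigel replicates 2 and 3 (0.038 and 0.055), against -0.50 without Matrigel replicate 1. The cause was not tested, except that subtraction removes counts of organoid genes. Co-cultured HSC replicate 1 was the shallowest library (6907479 counts), and what its depth limits was not tested.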

Other observations

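Genes in this part were chosen after their values were seen, within lists fixed before. In co-cultured HSC 28 of 29 hypoxia and glycolysis genes were higher and 1 lower (camera adjusted p = 3.44e-29, and 0.0176 with an estimated correlation), including Bnip3 (log2 fold change 2.63, adjusted p = 5.65e-08), Ldha (2.17, 5.09e-06) and Car12 (6.25, 4.11e-07). In co-cultured ICO 22 of 29 were higher and 0 lower (23 and 1 over the list alone, 2e-29, and 0.0767), including Ndrg1 (1.77, 6.23e-08) and Car9 (1.62, 1.6e-06). Of the same 29 genes, 24 were higher in ICO alone than in HSC alone, and 3 were lower. The organoid share was 28%, 14.5% and 41.9% in co-cultured HSC, against 34.3%, 12.7% and 4.05% in HSC alone. Organoid RNA may thus add to the increase in co-cultured HSC, and the size of that part was not estimated for this list. Retinoid genes moved both ways in co-cultured HSC, 10 higher and 6 lower of 26 (0.721): the retinal dehydrogenase Aldh1a2 had 630.6 against 4.38 CPM (0.000549), whereas Aldh1a1 had 5.55 against 71.0 CPM (3.17e-07). Interferon response genes had 19 lower and 4 higher of 25 (2.13e-06, and 0.231), including B2m (-2.08, 1.34e-05), and 20 lower over the list alone, in the comparison in which macrophage transcripts were also lower. Unfolded protein response genes had 15 higher and 1 lower of 20 (0.000444, and 0.189), and cholesterol biosynthesis genes 8 higher of 22 in HSC (9 over the list alone; 0.0386, 0.574 with an estimated correlation, and lost without mono-culture replicate 2 or 3 or co-culture replicate 2, at 0.137, 0.0588 and 0.0706) and 15 lower of 22 in ICO (1.37e-09, and 0.235).

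On plastic against day 0, all 25 interferon response genes were lower (adjusted p = 2.5e-16, and 0.124 with an estimated correlation), as were 20 of 23 immediate-early and heat shock genes (21 lower and 2 higher over the list alone; 2.66e-10, and 0.105), and 14 of 18 p53 and senescence genes were higher (2.39e-09, and 0.147). Macrophage, lymphocyte, endothelial and hepatocyte lists were also lower there, with 12 of 18, 5 of 6, 18 of 18 and 32 of 32 genes and adjusted p of 0.429, 0.147, 0.000788 and 0.000149 with an estimated correlation, so that only the endothelial and hepatocyte calls held. In Matrigel alone against day 0, 24 of 25 interferon genes and 20 of 23 immediate-early genes were lower (the latter 21 lower and 2 higher over the list alone), and both calls held with an estimated correlation (0.0301 and 0.0283), in the comparison in which 18 of 18 endothelial (0.000271), 31 of 32 hepatocyte (0.00237) and 5 of 6 lymphocyte genes (0.176) were also lower. Day 0 cells differ from cultured cells in isolation as well as in time, which these comparisons do not separate.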
